A study of Oryza sativa with 18 samples.

How the data were processed

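The comparisons rest on the deposited gene counts, which are raw counts per gene and library per the file headers. The same table holds deposited FPKM values per the file headers, which are counts scaled by library total and gene length. The FPKM values were used only to check the counts. Over 14683 genes with more than 20 counts, the gene length implied by count and FPKM had a largest ratio of 1.00004 between libraries, and 0 genes were at 0 in one unit and above it in the other. Per the submitters' processing notes the aligner was Bowtie 0.12.2 and the genome build was mm8. That build is a mouse genome, whereas the table lists rice loci on rice chromosomes. The rice build, the annotation release and the counting tool are not given in the sources used here. Strand use is not stated, so antisense or overlapping transcripts cannot be told apart from the listed gene, OsPHO1;2 included. Per the labels the RNA was extracted with the RNeasy Plant Mini Kit and sequenced from standard Illumina libraries.

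Of 55986 loci, 29055 had a count above 0 in any library and 20437 passed edgeR's filterByExpr with the 6 groups as its grouping. The genes that passed held between 99.8% and 100.0% of each library's counts. Library sizes were scaled by TMM. A quasi-likelihood fit with 6 group means over all 18 libraries (edgeR 4.0.16) gave 9 contrasts, each tested on both sides and adjusted by Benjamini-Hochberg over all genes, with adjusted p under 0.05 as the threshold. These are Ko1 against WT and OE against WT at each stage, 15DAF against 5DAF in each genotype, and the change of each genotype effect between the stages. CPM values are edgeR's counts scaled to library size, here the TMM-scaled one, and their error is the SD over 3 libraries. A prior count of 2 entered only the principal components and plots. A fold against a group with 0 counts in all its libraries was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts the ratio of counts is given with its 95% counting interval. Intervals and floors cover counting error only, since sequencing reads are not independent molecules.

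Gene lists were fixed before the data were examined, as were the contrasts, the alternatives and the rule for naming genes. Of 186 members fixed by rice locus, 183 were in the table, and 176 of these carried the expected RAP identifier. The symbols printed for list members come from these lists and the descriptions from the table. The lists, with the members tested, were phosphate transport and Pi-starvation response (26), photosynthetic light reactions (32), Calvin-Benson cycle (15), photorespiration (12), starch and sucrose metabolism and transport (24), chlorophyll synthesis (13), leaf senescence and chlorophyll breakdown (12), circadian clock (9), heat shock proteins (7), pathogenesis-related and jasmonate genes (12) and developing grain markers (5). Description words in the table gave the lists of cytosolic ribosomal proteins (268, some of which may be organellar by their description), WRKY transcription factors (68), histones (46) and early light-induced proteins (5). A list of plastid-encoded photosynthesis genes was not used, because the table holds no plastid chromosome. The RefSeq gene table in the reference shares no identifier with the count table and was not used. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 135 tests (15 lists and 9 contrasts), and again with an estimated correlation and with fry (limma 3.58.1).

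Genes are named by a rule with 4 parts. OsPHO1;2 is always named. From each list, for the genotype contrasts and for time in WT, up to 4 called members with the largest absolute log2 fold change are named, or up to 2 with the highest level if none was called. For the same contrasts, the 6 highest and 6 lowest called genes with a description are named if their mean is at least 1 CPM and all 3 libraries of one group lie beyond the 3 of the other. For the changes of effect, 3 genes in each direction are named on the same terms. Not every gene that the rule gives is printed. Genes named outside the rule are said to have been chosen after their values were seen.

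The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, adjusted p under 0.01, a fit of only the groups in the contrast, and leaving out each library in turn. An alternative pseudocount was planned for normalized values only and did not apply to counts. Leaving out the library labelled WT 5DAF replicate 3 was planned as 1 of the leave-one-out fits. Its use for every contrast and list, and the fit without 2 libraries, were chosen after seeing the data. In a self-test on simulated counts with the same design, 100 changed genes of each size were planted among 20437. For Ko1 against WT at 5DAF edgeR recovered 33.0% of the genes changed by 1 log2 unit and 81.0% of those changed by 2, with 4 unchanged genes called. For Ko1 against WT at 15DAF it recovered 38.0% and 74.0%, with 7 unchanged genes called. The simulation gave all libraries of a group the same mean per gene. On the real counts, Ko1 against WT at 5DAF called 3 genes with the library labelled WT 5DAF replicate 3 and 2803 without it. The recovered shares may therefore not hold for that comparison as run. R 4.3.3 ran the tests, and Python 3.11.15 with matplotlib 3.10.9 drew the plots.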

Results

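Flag leaves of rice (Oryza sativa) grown in a paddy field were profiled by RNA sequencing during grain filling. The labels give 3 genotypes of the phosphate exporter gene OsPHO1;2, namely the wild type (WT), the mutant line Ospho1;2-Ko1 (Ko1) and an overexpression line (OE). Leaves were taken at 5DAF and 15DAF, where DAF by its usual reading means days after flowering. The series title places the study in the regulation of flag leaf photosynthesis while the grain fills. Each of the 6 groups had 3 libraries, 18 in all. The total counts of the WT libraries were 16122046, 14270208 and 14122797 at 5DAF and 13622835, 14272933 and 18264909 at 15DAF. Those of the Ko1 libraries were 13284062, 15735053 and 13491403 at 5DAF and 15149924, 13223554 and 15871166 at 15DAF. Those of the OE libraries were 14303634, 14402095 and 14827031 at 5DAF and 16299258, 15160668 and 14747531 at 15DAF. Nothing in the labels says that replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

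The libraries separated by stage along the first principal component (35.8% of the variance) and Ko1 separated from the other genotypes along the second (24.9%). The library labelled WT 5DAF replicate 3 lay at −38.3 on the second component, whereas the other WT 5DAF libraries lay at 54.9 and 51.9. The Ko1 5DAF libraries lay at −18.0, −33.1 and −84.2. Across genes, the mean correlation of that library was 0.960 with the Ko1 5DAF libraries and 0.936 with its own group. A nearer other group was not particular to it. WT 5DAF replicates 1 and 2 were nearer to OE at 5DAF (0.968 and 0.956) than to their own group (0.950 and 0.947), which holds that library. Ko1 5DAF replicate 1 was nearer to WT at 5DAF (0.956 against 0.952). The library labelled WT 5DAF replicate 3 was kept under its label in every comparison. The count of called genes without it is given for each comparison that uses it. That reading of the library was made after the data were seen.

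**Figure D1:**
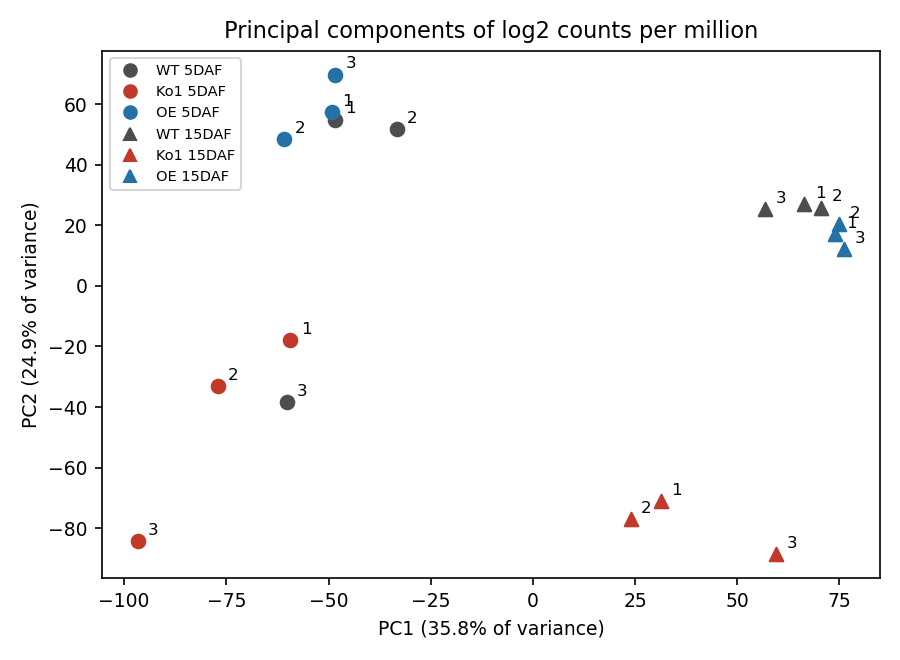
Each point is 1 library, placed by its first and second principal components of log2 CPM (counts scaled to library size), with colour for the genotype, marker shape for the stage and the replicate number beside it. The library labelled WT 5DAF replicate 3 sits at −38.3 on the second component, among the Ko1 5DAF libraries.

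The targeted gene OsPHO1;2 (LOC_Os02g56510, described as phosphate transporter 1) lies on chromosome 2 from 34609408 to 34615666, on a build not given in the sources used here. Its transcript was low in WT leaves, at 2.50 ± 0.925 CPM at 5DAF and 2.54 ± 0.737 CPM at 15DAF (SD, n = 3). The WT libraries read 1.72, 3.52 and 2.25 CPM at 5DAF and 1.78, 2.58 and 3.25 CPM at 15DAF. The OE libraries read 5.91, 8.89 and 9.74 CPM at 5DAF and 17.995, 4.75 and 29.5 CPM at 15DAF, each above every WT library. The Ko1 libraries read 3.38, 2.78 and 1.102 CPM at 5DAF and 6.10, 6.14 and 6.07 CPM at 15DAF. The kind of mutation in Ko1 is not stated, so the transcript level does not test that label. None of these differences passed edgeR's test, with log2 fold changes against WT of 1.71 (SE 0.513, edgeR adjusted p = 0.405) for OE at 5DAF and 2.77 (SE 0.519, edgeR adjusted p = 0.122) for OE at 15DAF. For Ko1 the values were −0.05 at 5DAF and 1.25 at 15DAF (edgeR adjusted p = 0.973 and 0.114). At 15DAF the OE difference passed without OE 15DAF replicate 2 (log2 3.21, edgeR adjusted p = 0.00733) and without the library labelled WT 5DAF replicate 3 (edgeR adjusted p = 0.0489). The second of these libraries is not in that comparison and acts on it only through the shared fit. Over the 7 leave-one-out fits of the OE difference at 15DAF, log2 fold changes ran from 2.15 to 3.21. Their edgeR adjusted p ran from 0.00733 to 0.786.

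**Figure D2:**
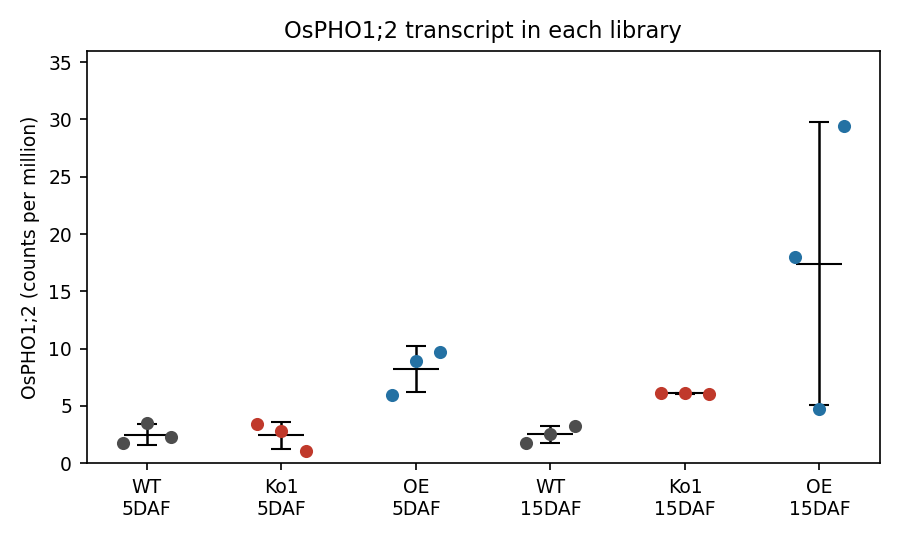
OsPHO1;2 in each library in CPM, with points for libraries and bars for the mean and SD of each group. Every OE library lies above every WT library, and the 3 Ko1 libraries of 15DAF lie between 6.07 and 6.14.

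Ko1 against WT at 15DAF asks how the flag leaf of the line with a mutated phosphate exporter differs, midway through grain filling. Effects of the mutation and of a different background of the line cannot be told apart here. Many phosphate-starvation genes were higher in Ko1 leaves. IPS1 (LOC_Os03g05334, chromosome 3, 2608931 to 2609586), a noncoding decoy of a phosphate-starvation microRNA, rose from 0.127 ± 0.219 to 242 ± 167 CPM (SD, n = 3). The SPX genes, whose proteins sense inositol phosphates, included 4 that rose. SPX5 (LOC_Os03g29250, chromosome 3, 16645316 to 16646422) went from 0 counts in WT to 24.1 ± 12.2 CPM, at least 371-fold higher. SPX3 (LOC_Os10g25310) was higher by a count ratio of 409 (counting interval 139.6 to 1987), and read 10.9, 9.84 and 53.9 CPM in the Ko1 libraries. SPX1 rose by 4.39 log2 units and SPX2 by 3.24. GDPD2 (LOC_Os02g31030, chromosome 2, 18537041 to 18540912), a glycerophosphodiester phosphodiesterase, went from 14.7 ± 3.64 to 639 ± 216 CPM. LOC_Os08g20420 (chromosome 8, 12266091 to 12269671), described as the galactolipid synthase MGD2, went from 0 counts to 58.2 ± 34.3 CPM, at least 939-fold higher. The sulfolipid synthesis genes SQD1 and SQD2 rose by 1.64 and 1.81 log2 units and the acid phosphatase PAP10a by 2.78. The list also holds transport and regulatory genes, and being in it does not mean that starvation raises a gene. Of these the ubiquitin conjugase gene PHO2 rose by 2.14 and the transporter of the vacuole SPX-MFS2 by 2.39. SPX-MFS1 fell by 3.32, from 65.1 ± 5.94 to 6.55 ± 1.89 CPM. PHR1 and PHR2, which encode the regulators of this response, did not pass, at −0.02 and 0.05. SPX1, SPX2, SQD1, SQD2, PAP10a, PHO2, SPX-MFS1, SPX-MFS2, PHR1 and PHR2 were chosen after their values were seen.

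In that list 16 of 26 members were higher and 1 lower by edgeR, and 19 were higher and 2 lower adjusted over the list alone. Camera called the list (adjusted p = 2.28e-14), and the call held with an adjusted p = 0.0183 with an estimated correlation. By edgeR, IPS1 had a log2 fold change of 10.61 (SE 2.15, edgeR adjusted p = 0.00616) and GDPD2 one of 5.44 (SE 0.678, edgeR adjusted p = 0.000119). For SPX5, SPX3 and LOC_Os08g20420 the edgeR adjusted p was 0.00464, 0.000684 and 4.17e-06.

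**Figure D3:**
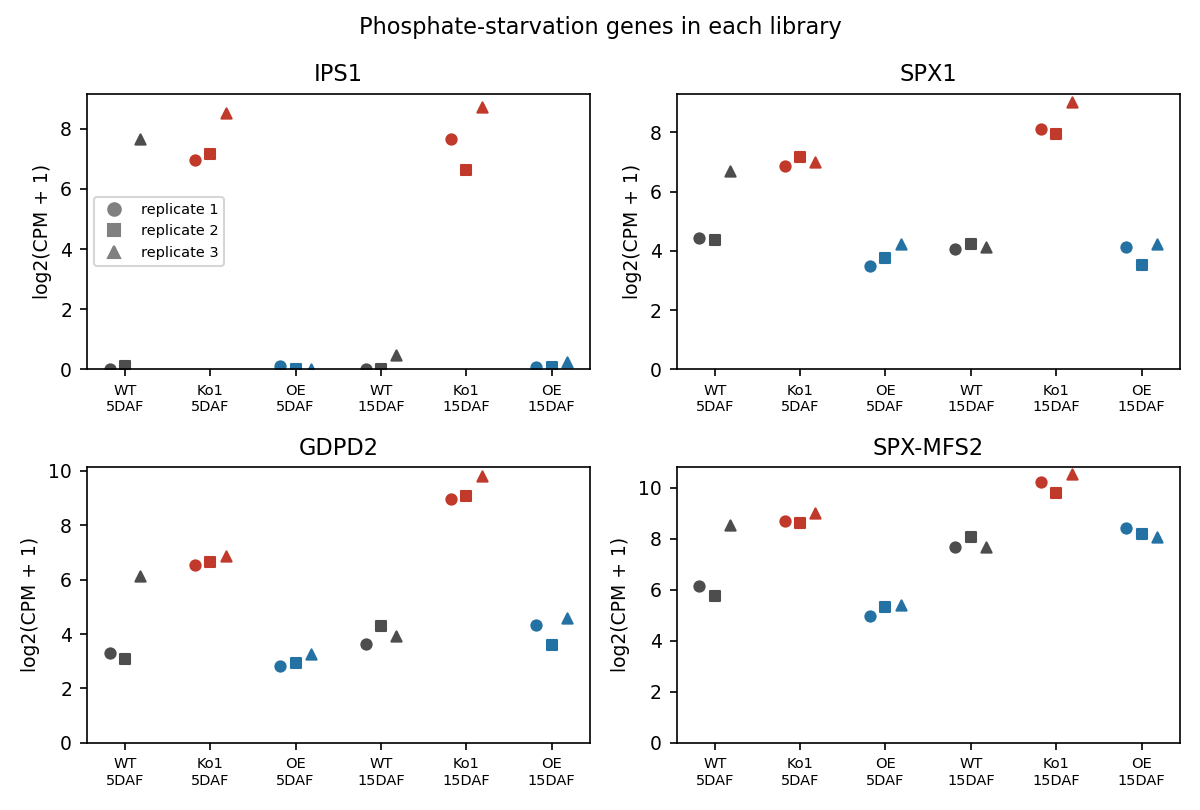
Phosphate-starvation genes in each library as log2 of CPM plus 1, by group, with marker shape for the replicate number. IPS1 read 203, 98.4 and 426 in the Ko1 15DAF libraries, and 200 in the library labelled WT 5DAF replicate 3 against 0 and 0.0766 in the other WT 5DAF libraries.

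At the same stage 5 of 24 starch and sucrose genes of Ko1 leaves were higher and 78 of 268 ribosomal protein genes lower. SPS11, a sucrose-phosphate synthase, rose from 8.54 ± 0.977 to 108 ± 75.3 CPM (SD, n = 3; log2 3.66). The plastid glucose-phosphate translocator GPT1 rose from 17.41 ± 4.80 to 49.4 ± 8.61 CPM, and the starch synthases GBSSII and SSI by 1.26 and 1.21 log2 units. The fifth starch and sucrose gene higher by edgeR was AGPS2 (1.12, chosen after its value was seen), and 6 of the list were higher and 1 lower adjusted over the list alone. Camera called that list (adjusted p = 0.0212, adjusted p = 0.503 with an estimated correlation). GBSSII and SSI did not pass without Ko1 15DAF replicate 3 (0.92 and 0.98) or without any 1 WT 15DAF library (GBSSII 1.21 to 1.32, SSI 1.06 to 1.36). Of 268 ribosomal protein genes 78 were lower and 0 higher by edgeR, and 124 lower and 1 higher adjusted over the list alone. DESeq2 called 108 lower and 1 higher, and at an unadjusted p under 0.05 the counts were 146 and 2. LOC_Os05g30530, a 40S protein S4 gene, fell from 46.4 ± 0.850 to 25.1 ± 0.0636 CPM, and LOC_Os07g01870, an L13 gene, from 47.2 ± 5.72 to 25.8 ± 1.96 CPM, and both calls held in every leave-one-out fit. LOC_Os06g46930 (L24) and LOC_Os03g38000 (S3-1) each fell by 0.89 log2 units. The L24 call ended without any 1 library of the contrast (−1.01 to −0.78), and the S3-1 call ended without WT 15DAF replicates 1 or 3 or Ko1 15DAF replicates 1 or 2 (−0.87 to −0.70). Camera called this list lower (adjusted p = 3.35e-20, adjusted p = 0.487 with an estimated correlation).

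Few photosynthesis genes passed in Ko1 at 15DAF. Only Lhcb1.2 (LOC_Os01g52240) of 32 light-reaction genes was higher, from 0.671 ± 0.221 to 20.7 ± 20.9 CPM (SD, n = 3), and 1 was higher adjusted over the list alone. Of 15 Calvin-Benson genes 1 was higher, cpFBPase by 0.64 log2 units, a call that ended without any 1 WT 15DAF library or without Ko1 15DAF replicates 1 or 3 (0.56 to 0.69), and 2 were higher adjusted over the list alone. Of 12 photorespiration genes 0 passed by edgeR, 0 by DESeq2, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with CATC at 0.00 and GLO1 at −0.56. Of 13 chlorophyll synthesis genes 3 were higher, GLK2 by 1.67, CHLM by 1.60 and DVR by 1.28, and 3 were higher adjusted over the list alone. Ko1 15DAF replicate 2 set much of this. It read 44.8 CPM for Lhcb1.2 against 7.86 and 9.40 in the other replicates, 106 for GLK2 against 38.9 and 27.1, and 58.0 for CHLM against 11.6 and 11.1. SPS11 read 194 CPM there against 55.8 and 74.2. Without it GLK2 and CHLM did not pass (0.88 and 0.36). CHLM also ended without any 1 WT 15DAF library (1.33 to 1.80), GLK2 without WT 15DAF replicates 2 or 3 (1.60 and 1.64) and DVR without WT 15DAF replicate 2 (edgeR adjusted p = 0.0672). Camera gave adjusted p = 0.693 for light reactions, 0.793 for Calvin-Benson, 0.0946 for photorespiration and 0.813 for chlorophyll synthesis.

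Senescence, clock and stress lists gave few calls at 15DAF. Of 12 senescence genes Osl57 was lower by 0.64 log2 units, a call that ended without any 1 library of the contrast (−0.72 to −0.56), and 0 passed adjusted over the list alone. Of 9 clock genes PRR73 was higher, at 1015 ± 102 CPM against 200 ± 40.2 in WT (SD, n = 3), with OE at 670 ± 120 CPM, and 1 was higher adjusted over the list alone. Of 7 heat shock genes HSP101 was higher by 3.27, and of 12 pathogenesis and jasmonate genes MYC2 by 1.78, each list having 1 adjusted over the list alone. MYC2 read 44.7 CPM in Ko1 15DAF replicate 2 against 18.05 and 13.7, and did not pass without it or without WT 15DAF replicates 2 or 3 (1.66 and 1.75). Of 5 grain markers BEIIb was higher by 1.66, at 8.68 ± 1.26 CPM, and 2 were higher adjusted over the list alone. Of 68 WRKY genes 6 were higher and 4 lower, and 6 and 6 adjusted over the list alone, led by WRKY9 (LOC_Os01g18584) at 2.91, which did not pass without Ko1 15DAF replicate 2 (1.65) or without any WT 15DAF library (2.83 to 3.12). Of 46 histone genes 1 was higher and 1 lower, and 1 was higher adjusted over the list alone. Of 5 early light-induced genes 0 passed by edgeR or adjusted over the list alone, 1 by DESeq2 and 1 at an unadjusted p under 0.05. Camera called none of these 8 lists, the lowest adjusted p being 0.0517, for senescence. In the fit without the library labelled WT 5DAF replicate 3, which this comparison does not use, camera called senescence lower (adjusted p = 0.0352, adjusted p = 0.558 with an estimated correlation). There 3 of 12 senescence genes were lower and 0 higher by edgeR, and 4 lower and 1 higher adjusted over the list alone.

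Some of the largest differences at 15DAF were genes read in one genotype and at 0 in another. Retrotransposon gene LOC_Os05g45160 (chromosome 5, 26218549 to 26222589) read 41.9 ± 2.58 CPM in WT and 0 counts in Ko1 (SD, n = 3), at least 644-fold lower. The CACTA transposon genes LOC_Os10g20280 and LOC_Os07g05850 were at least 421-fold and 337-fold lower, the Mutator gene LOC_Os08g33550 at least 387-fold, retrotransposon gene LOC_Os08g13080 at least 201-fold and zinc knuckle gene LOC_Os08g33580 at least 142-fold, whose call ended without WT 15DAF replicates 1 or 2 (edgeR adjusted p = 0.0532 and 0.0522). In the OE 15DAF libraries LOC_Os05g45160, LOC_Os10g20280, LOC_Os08g33550 and LOC_Os08g33580 also had 0 counts. Higher in Ko1 were the ureide permease gene LOC_Os12g31850 (at least 892-fold, 56.2 ± 6.88 CPM), the rho-GTPase-activating gene LOC_Os04g47330 (at least 274-fold) and the haemolysin-III gene LOC_Os12g32640 (at least 273-fold). LOC_Os12g32640 read 5.53, 13.2 and 32.3 CPM in the Ko1 15DAF libraries. LOC_Os12g31850 read 60.8 ± 8.13 CPM in OE at 15DAF (edgeR adjusted p = 0.134 against WT). The transposon gene LOC_Os10g14230 was at least 283-fold higher and did not pass without any 1 WT 15DAF library or without Ko1 15DAF replicates 1 or 2 (edgeR adjusted p from 0.0665 to 0.111).

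Over all genes, edgeR called 2240 of 20437 for Ko1 against WT at 15DAF, 1334 higher and 906 lower, of which 1073 and 301 changed at least 2-fold. The count was 815, 814 and 915 without WT 15DAF replicates 1, 2 and 3, and 1369 without Ko1 15DAF replicate 3. DESeq2 called 3498.

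Ko1 against WT at 5DAF asks for the same difference early in filling. With all libraries the Pi-starvation genes were spread widely within WT. IPS1 read 124, 142 and 363 CPM in the Ko1 libraries, and GDPD2 read 91.0, 101 and 117 CPM. In WT, IPS1 read 0 and 0.0766 CPM in replicates 1 and 2 and 200 CPM in the library labelled replicate 3, and GDPD2 read 8.83, 7.36 and 69.9 CPM. The low-affinity cation transporter gene LOC_Os06g38120 rose from 30.02 ± 3.51 to 66.9 ± 5.98 CPM (SD, n = 3), and receptor kinase gene LOC_Os11g47240 fell from 160.5 ± 26.697 to 65.4 ± 6.56 CPM.

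By edgeR 3 genes were called, 1 higher and 2 lower, with 3965 at an unadjusted p under 0.05 and 760 by DESeq2. They were LOC_Os06g38120 (log2 1.15, edgeR adjusted p = 0.0385), LOC_Os11g47240 (−1.29, edgeR adjusted p = 0.0385) and LOC_Os10g35160, an expressed protein chosen after its values were seen (−4.65, edgeR adjusted p = 0.0109). The count was 1 without WT 5DAF replicate 1, 0 without WT 5DAF replicate 2 and 0 without any 1 Ko1 5DAF library, so LOC_Os06g38120 and LOC_Os11g47240 passed in 1 of 6 leave-one-out fits, the one without the library labelled WT 5DAF replicate 3. Both also passed without that library and Ko1 5DAF replicate 3 together. Neither passed with the replicate number as a block or in a fit of only the groups of the contrast (edgeR adjusted p = 0.0766 and 0.504 for each). Without the library labelled WT 5DAF replicate 3 it was 2803, 1255 higher and 1548 lower. Of the members of all lists 0 passed by edgeR with all libraries, 125 at an unadjusted p under 0.05 and 26 by DESeq2. Adjusted over the list alone, 5 Pi-list genes were higher and 2 lower, 7 chlorophyll synthesis genes were lower, and 6 senescence genes were lower and 1 higher. Camera called 9 of 15 lists, among them chlorophyll synthesis (adjusted p = 5.17e-05, adjusted p = 0.487 with an estimated correlation), and none of the 9 with an estimated correlation.

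Without that library some Pi-starvation genes were higher and some photosynthesis and chlorophyll synthesis genes lower in Ko1 leaves at 5DAF. IPS1 and SPX3, each with 1 count in WT there, were higher by count ratios of 5748 (counting interval 1031 to 227039) and 30.5 (5.22 to 1228). GDPD2 was higher by 3.66 log2 units, SPX-MFS2 by 2.84 and SPX1 by 2.66, and SPX-MFS1 was lower by 1.97. Of 27 Pi-list genes 8 were higher and 2 lower, and 8 and 3 adjusted over the list alone. Of 13 chlorophyll synthesis genes 9 fell, with GLK1 at −2.07, CAO1 at −1.52, CRD1 at −1.32 and PORB at −1.29, and 9 adjusted over the list alone. Of 15 Calvin-Benson genes 6 fell, with RCA at −1.79, FBA1 at −1.23, PRK at −1.13 and SBPase at −1.13, and 6 adjusted over the list alone. Of 32 light-reaction genes 6 fell, with Lhca4 at −1.42 and Lhcb3 at −1.31, and 8 adjusted over the list alone. Of 12 photorespiration genes 4 fell, among them Fd-GOGAT at −1.08, and 7 adjusted over the list alone. Camera called these lists (adjusted p = 3.48e-05 for Pi, 4.15e-07 for chlorophyll synthesis, 5.79e-05 for Calvin-Benson, 0.000393 for light reactions and 0.000290 for photorespiration), with an adjusted p = 0.267, 0.351, 0.525, 0.610 and 0.546 with an estimated correlation. All genes in this paragraph were chosen after their values were seen. In the same fit 1276 genes were called at both stages, 704 higher at both (111 expected if the calls were independent), 562 lower at both (91.7 expected) and 10 in opposite directions.

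The change of the Ko1 effect between the stages was tested directly. It passed for 113 genes, 94 with a more positive effect at 15DAF and 19 with a more negative one. In the Pi list the effect rose for PHO2 (1.93), SPX2 (2.48), PAP10a (2.01), SQD1 (2.28), SQD2 (1.90) and PHF1 (0.99), which are 6 of 26 by edgeR, and 12 rose and 1 fell adjusted over the list alone. These 6 genes were chosen after their values were seen. The cytochrome P450 gene LOC_Os01g43750 (chromosome 1, 25066171 to 25068299) moved the other way. It read 53.0 ± 3.75 CPM in Ko1 against 29.4 ± 6.20 in WT at 5DAF, and 39.4 ± 7.82 against 132 ± 5.34 at 15DAF (SD, n = 3; change −2.60, edgeR adjusted p = 0.000482).

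Camera called the Pi list (adjusted p = 5.76e-15), with an adjusted p = 0.0183 with an estimated correlation and 0.1998 with an estimated correlation without the library labelled WT 5DAF replicate 3. Without that library 84 genes passed, 66 of them among the 113. The count was 35, 37 and 52 without WT 15DAF replicates 1, 2 and 3, 43 and 56 without Ko1 5DAF replicates 2 and 3, and 55 without Ko1 15DAF replicate 3. DESeq2 called 307.

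OE against WT asks how the leaf of the overexpression line differs. Effects of more exporter transcript and of a different background of the line cannot be told apart here. Few genes passed at either stage with all libraries, and 3 passed at both, all higher in OE. Of 12 genes read in every WT 15DAF library and at 3 counts or fewer in Ko1 and in OE at 15DAF, chosen after their values were seen, edgeR called 0 for OE at either stage with all libraries. Leaving out the library labelled WT 5DAF replicate 3, it called all 12 at both stages. At 15DAF their edgeR adjusted p ran from 0.226 to 0.579 with that library and from 3.75e-06 to 0.0284 without it. The 15DAF comparison does not hold that library, which acts on it only through the shared fit, where the spread is pooled over the 6 groups. Retrotransposon gene LOC_Os06g05230 (chromosome 6, 2343537 to 2349553) had 0 counts in every WT and Ko1 library. It read 17.6 ± 10.1 CPM in OE at 5DAF and 39.4 ± 15.3 CPM at 15DAF (SD, n = 3), at least 248-fold and 615-fold higher than WT. Retrotransposon gene LOC_Os03g31560 (chromosome 3, 18004456 to 18011507) read 7.75 ± 2.76 and 10.4 ± 2.74 CPM, at least 111-fold and 163-fold higher. The third was LOC_Os11g02720, an expressed protein (3.89 and 3.51). At 5DAF the pumilio-family gene LOC_Os05g26040 rose by 2.61 and urea transporter gene LOC_Os10g42960 fell from 51.5 ± 2.83 to 0.976 ± 0.862 CPM (log2 −5.72). Late embryogenesis abundant gene LOC_Os01g21250 fell by 1.74, LTPL124 (LOC_Os04g52260) by 1.59 and LOC_Os03g37140, an expressed protein, by a count ratio of 62.5 (counting interval 21.1 to 306). At 15DAF the transferase gene LOC_Os06g48560 rose from 3.54 ± 0.627 to 25.9 ± 7.998 CPM (log2 2.86) and LOC_Os04g58050, an expressed protein, fell by 5.77. LOC_Os11g02720, LOC_Os03g37140 and LOC_Os04g58050 were chosen after their values were seen.

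By edgeR 8 genes were called for OE at 5DAF, 4 higher and 4 lower, and 5 at 15DAF, 4 higher and 1 lower. DESeq2 called 94 and 25. Both retrotransposon calls held in every leave-one-out fit. LOC_Os06g48560 did not pass without any 1 WT or OE 15DAF library (2.59 to 3.01). LOC_Os10g42960 did not pass without OE 5DAF replicates 1 or 2 (−5.67 and −5.21). LOC_Os05g26040 did not pass without WT 5DAF replicate 2, the library labelled replicate 3 or any 1 OE 5DAF library (2.45 to 2.71). LOC_Os01g21250 and LOC_Os04g52260 did not pass without WT 5DAF replicate 2 or any 1 OE 5DAF library (−1.97 to −1.44 and −1.66 to −1.50). The 5DAF count was 60 without WT 5DAF replicate 1, 38 without the library labelled WT 5DAF replicate 3, 5 without WT 5DAF replicate 2, 4 without OE 5DAF replicate 1 and 5 without either other OE 5DAF library. The 15DAF count was 29 without the library labelled WT 5DAF replicate 3 and 3 without any 1 WT 15DAF library. The first of these libraries enters the 15DAF comparison only through the shared fit. Of the members of all lists 0 passed by edgeR at either stage with all libraries. At 5DAF 34 had an unadjusted p under 0.05 and 3 passed by DESeq2, and at 15DAF 31 and 3.

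In OE camera at its preset correlation of 0.01 called photosynthesis lists as sets, without single calls by edgeR. Camera with an estimated correlation and fry called 0 of 15 lists for OE at either stage. The estimated correlation at 15DAF was 0.481 for light reactions, 0.549 for Calvin-Benson and 0.601 for photorespiration. These values come from the fit without the library labelled WT 5DAF replicate 3. At 15DAF the light-reaction genes were lower on average (mean log2 −0.41, camera adjusted p = 5.71e-13, adjusted p = 0.487 with an estimated correlation), with 0 of 32 members passing by edgeR, 10 at an unadjusted p under 0.05 and 0 by DESeq2. Lhcb1.1 (LOC_Os01g41710) read 1690.4 ± 182 CPM in OE against 2251 ± 464 CPM in WT (SD, n = 3). The Calvin-Benson list was lower and the starch list higher (camera adjusted p = 0.00152 and 0.000264, with an adjusted p = 0.565 and 0.474 with an estimated correlation). Photorespiration and pathogenesis genes were lower as sets (camera adjusted p = 0.0182 and 0.0212, with an adjusted p = 0.642 and 0.538 with an estimated correlation). At 5DAF camera called Calvin-Benson, photorespiration and clock genes higher and early light-induced genes lower (adjusted p = 0.0143, 0.000264, 0.0164 and 0.0252), and none with an estimated correlation. Without the library labelled WT 5DAF replicate 3 the adjusted p of camera was 0.893 for Calvin-Benson, 0.283 for photorespiration, 0.0337 for the clock and 4.67e-05 for early light-induced genes, with an adjusted p = 0.569 and 0.267 with an estimated correlation for the last 2. Adjusted over the list alone, 1 Pi-list gene was higher and 5 lower and 3 early light-induced genes lower at 5DAF. At 15DAF 2 Pi-list genes, 1 starch gene and 1 clock gene were higher adjusted over the list alone. Leaving out that library, 0 Pi-list genes were higher and 0 lower at 5DAF adjusted over the list alone, 3 early light-induced genes were lower and 1 clock gene higher. At 15DAF camera's call of the pathogenesis list ended in that fit (adjusted p = 0.0671).

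The effects of Ko1 and OE were compared because the labels name a mutant and an overexpression line of OsPHO1;2, while both use the same WT libraries. Their OsPHO1;2 transcript was not opposed at 15DAF. There every Ko1 and OE library lay above every WT library, though neither difference passed edgeR's test. At 15DAF LOC_Os06g48560 was higher and LOC_Os04g58050 lower in both lines, 2 shared calls against 0.548 expected if the calls were independent. Across genes, which are not independent replicates, the log2 fold changes of Ko1 and OE had a correlation of 0.361 and a covariance of 0.238 at 15DAF. Over 20 simulations of unchanged groups against shared WT libraries, the correlation was 0.503 and the covariance 0.127. At 5DAF the correlation was 0.172 (0.503 simulated) and the covariance 0.110 (0.123 simulated), with 0 shared calls by edgeR against 0.00117 expected. Without the library labelled WT 5DAF replicate 3 the values at 5DAF were 0.432 (0.618 simulated) and 0.409 (0.205 simulated), with 31 shared calls against 5.10 expected, 8 higher and 22 lower in both lines. These simulations kept the genes and the spread per gene of the fit with all libraries. The observed values come from a refit over 20900 genes without that library. The simulated values are thus of another setting and cannot decide on an excess there. At 15DAF the fit without that library shared 23 calls against 4.27 expected, 7 higher and 16 lower in both lines. At each stage its shared lower calls include the 12 genes read in WT and near 0 in both lines at 15DAF. Those genes were chosen for low counts in both lines, so they cannot count as evidence of a shared response. The WT libraries of a stage were not split between the lines, so part of any excess may come from shared controls.

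Time in WT leaves compares 15DAF with 5DAF. Leaf age cannot be told apart here from the conditions of each harvest, such as weather or time of day. This holds for time in Ko1 and OE too. Between 5DAF and 15DAF most light-reaction genes and some chlorophyll synthesis genes fell, while some senescence, starch and early light-induced genes rose. Lhcb1.2 fell from 33.1 ± 14.9 to 0.671 ± 0.221 CPM (SD, n = 3; log2 −5.63, edgeR adjusted p = 6.37e-05), PsbR1 by 2.14, Lhcb6 by 1.95 and PsaG by 1.87 log2 units. The Rubisco small subunit gene RBCS4 fell by 1.38 and PGK by 0.84. PORA, a protochlorophyllide reductase, fell from 245 ± 15.0 to 38.2 ± 10.6 CPM, CHLM by 2.22, PORB by 1.69 and CHLI by 1.17. The stay-green gene SGR (LOC_Os09g36200, chromosome 9, 20868717 to 20871108) rose from 4.96 ± 4.49 to 71.9 ± 8.59 CPM (log2 3.87, edgeR adjusted p = 7.81e-05). Glutamine synthetase GS1;1 rose by 1.51, PAO by 1.18 and NYC3 by 0.97. The starch synthase SSI rose by 1.74, AGPS1 by 1.38, the sucrose transporter SUT2 by 1.36 and SPS1 by 1.13. Early light-induced gene LOC_Os07g08160 rose from 17.6 ± 11.2 to 773 ± 162 CPM (log2 5.46, edgeR adjusted p = 9.89e-06), LOC_Os07g08150 by 5.08 and LOC_Os01g14410 by 5.05.

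By edgeR 20 of 32 light-reaction genes were lower and 1 higher (25 and 1 adjusted over the list alone), and 4 of 13 chlorophyll synthesis genes were lower (8 adjusted over the list alone). Of 12 senescence genes 4 were higher and 2 lower (5 and 3 adjusted over the list alone), of 24 starch and sucrose genes 6 and 1 (9 and 3), and of 5 early light-induced genes 3 were higher (3). Of 12 pathogenesis and jasmonate genes 5 were lower (6 adjusted over the list alone), led by PR1b at −1.75 and PR1a at −1.74. Of 268 ribosomal genes 32 were lower and 1 higher (32 and 0 adjusted over the list alone). Camera called these 7 lists, with adjusted p from 5.71e-13 for light reactions to 0.0216 for senescence, and none with an estimated correlation, the lowest being 0.395. Of 15 Calvin-Benson genes 2 were lower (2 adjusted over the list alone), of 12 photorespiration genes 1 was higher (1), of 9 clock genes LUX was lower at −0.84 (1), of 7 heat shock genes 2 were higher (2), and of 5 grain markers RPBF was higher at 2.45 (1). Of 68 WRKY genes 5 were higher and 6 lower (5 and 6 adjusted over the list alone), and of 46 histone genes 3 and 3 (2 and 2).

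In the fit without the library labelled WT 5DAF replicate 3, over the same change in WT, 24 of 32 light-reaction genes were lower and 1 higher (26 and 1 adjusted over the list alone) and 9 of 13 chlorophyll synthesis genes lower (11). Of 12 senescence genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone), of 24 starch and sucrose genes 3 and 2 (3 and 2), and of 5 early light-induced genes 3 were higher (3). Of 13 pathogenesis and jasmonate genes 2 were lower (2 adjusted over the list alone), of 268 ribosomal genes 31 (28) and of 15 Calvin-Benson genes 4 (5). In that fit camera called light reactions, chlorophyll synthesis, starch, early light-induced, ribosomal and Calvin-Benson genes (adjusted p = 6.35e-18, 5.41e-07, 0.0371, 0.000237, 0.00260 and 0.0381), and none with an estimated correlation, the lowest being 0.267. Camera's calls of the senescence and pathogenesis lists ended (adjusted p = 0.121 and 0.105).

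The naming rule gave 57 called genes for time in WT, and 16 of these calls ended in at least 1 leave-one-out fit. PR1b passed only without WT 5DAF replicate 1 (−2.08 to −1.48 over 6 fits). PR1a ended without WT 5DAF replicate 2, the library labelled replicate 3 or WT 15DAF replicates 2 or 3 (−1.81 to −1.46). AGPS1 ended without WT 5DAF replicate 1, the library labelled replicate 3 or WT 15DAF replicates 2 or 3 (1.15 to 1.36). PGK ended without WT 5DAF replicates 1 or 2 or WT 15DAF replicates 2 or 3 (−0.85 to −0.72), RPBF without WT 5DAF replicate 1, the library labelled replicate 3 or WT 15DAF replicate 3 (1.99 to 2.31), and CHLI without WT 15DAF replicate 2 (−1.12). CATC, higher by 0.94, ended without the library labelled WT 5DAF replicate 3 or any 1 WT 15DAF library (0.68 to 0.92). HSP17.4, higher by 2.33, ended without WT 5DAF replicate 1, the library labelled replicate 3 or WT 15DAF replicate 1 (1.83 to 2.13), and HSFA2c, higher by 0.95, without WT 15DAF replicate 1 (0.80). LOX2, at −1.32, passed in none of the 6 fits (−1.54 to −1.21). WRKY gene LOC_Os09g25060, at −2.43, ended without WT 5DAF replicate 2 or WT 15DAF replicates 2 or 3 (−2.23 to −1.76). WRKY gene LOC_Os07g27670, higher by 2.39, ended without WT 15DAF replicate 1 (2.15), and histone gene LOC_Os05g49860, higher by 0.64, passed only without WT 5DAF replicate 2 (0.48 to 0.78 over 6 fits). The other 3 are IPS1, SPX1 and PT3.

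In the Pi list 1 gene, SPX-MFS1, was higher at 15DAF in WT by 2.95, and 7 were lower (1 and 8 adjusted over the list alone). In the fit without the library labelled WT 5DAF replicate 3, 2 of 27 were higher and 4 lower (2 and 4 adjusted over the list alone), and the falls of IPS1, SPX1 and PT3 did not pass. IPS1 had a log2 fold change of −8.75 with it. Without it IPS1 had 1 count at 5DAF and 7 at 15DAF, a count ratio of 4.02 (counting interval 0.516 to 181). SPX1 had a log2 fold change of −1.51 with it and −0.29 without it (edgeR adjusted p = 0.0394 and 0.581, from 0.0947 to 0.116 without 1 WT 15DAF library). PT3 was lower by a count ratio of 27.7 (counting interval 4.53 to 1136) and also did not pass without any 1 WT 15DAF library (edgeR adjusted p = 0.0529 to 0.112). Its WT 5DAF counts were 1 and 1 in replicates 1 and 2 and 23 in the library labelled replicate 3, against 0, 1 and 0 at 15DAF.

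Single genes with the largest changes over time in WT came from several classes. The uORF-containing gene LOC_Os03g19370 was at least 126-fold higher at 15DAF and 4F5 family gene LOC_Os05g33700 at least 36.1-fold. The MATE efflux gene LOC_Os11g03484 rose by 6.55 log2 units. Peroxidase gene LOC_Os02g14440 fell from 90.8 ± 53.9 to 0.403 ± 0.447 CPM (SD, n = 3). The helix-loop-helix gene LOC_Os01g72370 was at least 38.4-fold lower and glutaredoxin gene LOC_Os11g43520 at least 33.6-fold. Glycosyl hydrolase gene LOC_Os05g15770 fell by 7.96, and read 9.11 and 5.75 CPM in WT 5DAF replicates 1 and 2 and 345 in the library labelled replicate 3. By edgeR 3418 genes were called, 1548 higher and 1870 lower, of which 840 and 1258 changed at least 2-fold. The count was 3114 without the library labelled WT 5DAF replicate 3, 2550 of them among the 3418, and 2080 and 1907 without WT 15DAF replicates 1 and 2.

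Time in Ko1 and OE leaves gave 4102 and 5455 called genes by edgeR, and WT shared most of its calls with OE. Of the WT calls 2757 were called in OE, 2756 in the same direction (912 expected if independent), and 2200 in Ko1, 2184 in the same direction (686 expected). Leaving out the library labelled WT 5DAF replicate 3, WT shared 2830 calls with OE, 1 of them in opposite directions, and 2113 with Ko1, 17 of them in opposite directions. The fall of light-reaction genes appeared in each genotype, with 16 of 32 lower in Ko1 and 26 in OE, and 1 higher in each (17 and 26 lower and 1 higher in each adjusted over the list alone). Of 24 starch and sucrose genes 10 rose and 0 fell in Ko1 and 12 rose and 2 fell in OE (11 and 0, and 13 and 2, adjusted over the list alone), with SSI at 3.25 and 2.82. SGR rose by 3.98 and 5.87. Chlorophyll synthesis genes fell in OE, 10 of 13 (11 adjusted over the list alone). In Ko1 1 chlorophyll synthesis gene was higher and 0 lower by edgeR, with 3 higher and 3 lower at an unadjusted p under 0.05, 2 higher and 1 lower by DESeq2, and 0 adjusted over the list alone. The change of the Ko1 effect called 0 of these 13 genes by edgeR, 1 by DESeq2 and 6 at an unadjusted p under 0.05. Leaving out the library labelled WT 5DAF replicate 3, it called 1 of the 13 by edgeR, and 9 were higher adjusted over the list alone. Ribosomal protein genes fell, 118 of 268 in Ko1 and 40 in OE (144 and 36 adjusted over the list alone), and 1 and 6 rose (3 and 3). In the Pi list 11 genes rose and 1 fell in Ko1 (12 and 1 adjusted over the list alone), and 3 rose and 4 fell in OE (3 and 4). SGR, SSI and the lists of this paragraph in Ko1 and OE lay outside the naming rule, and the 2 genes were chosen after their values were seen. In Ko1 the count was 2725 without Ko1 15DAF replicate 3.

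The change of the OE effect between the stages passed for 0 genes by edgeR, with 1226 at an unadjusted p under 0.05 and 13 by DESeq2. It was 3 without WT 5DAF replicate 1 and 0 without any other library. Over the 135 tests of lists camera called 56, camera with an estimated correlation 2 and fry 26. Fry's p tests whether the genes of a set move, on balance, one way, and it compares the set with no other genes or sets.

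**Figure D4:**
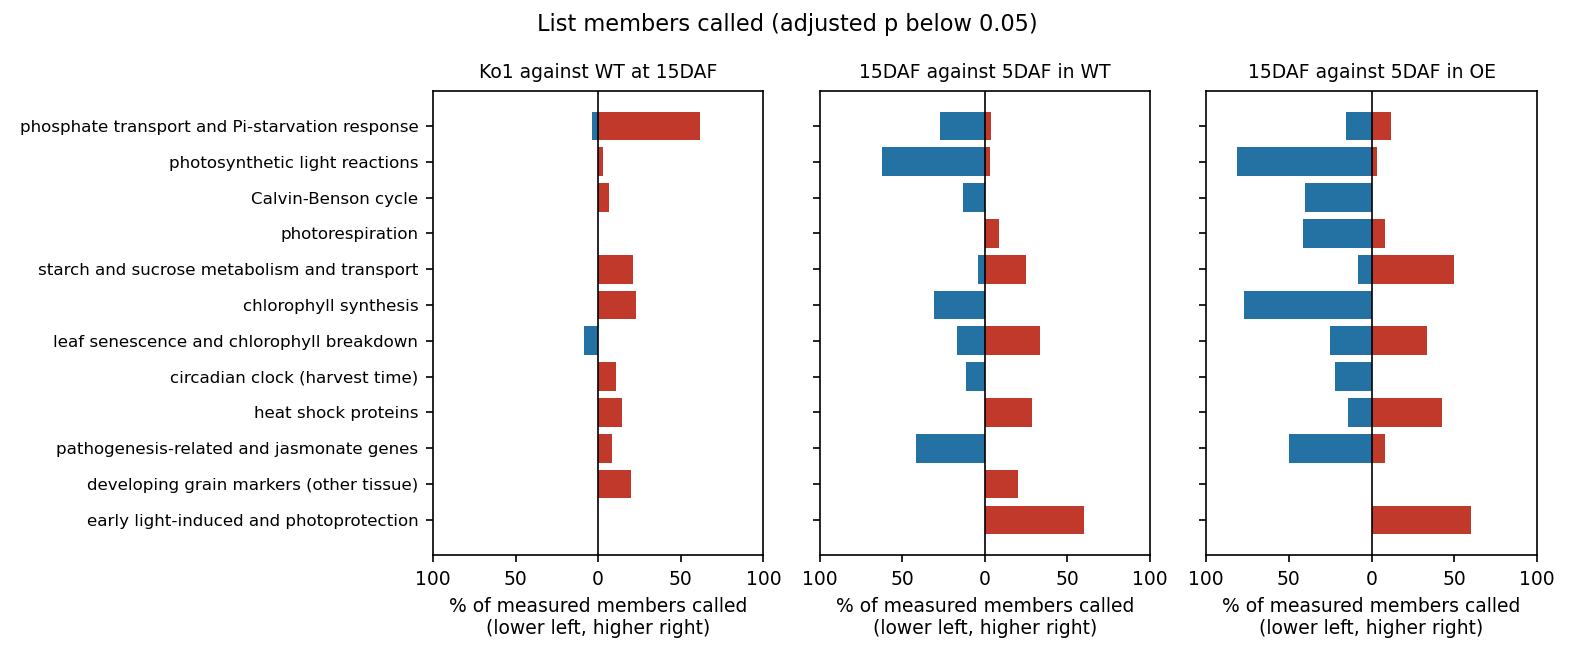
Percent of the measured members of each list shown that edgeR called (adjusted p below 0.05), lower to the left in blue and higher to the right in red. The panels are Ko1 against WT at 15DAF and 15DAF against 5DAF in WT and in OE. The lists of ribosomal proteins, WRKY transcription factors and histones are not shown. In the Pi list 16 of 26 members are higher in Ko1, and in the light-reaction list 20 of 32 are lower over time in WT and 26 in OE.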

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

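The results of this part are those for which a test of the difference between 5DAF and 15DAF passed, by edgeR for genes and by camera for lists. The counts over other splits were planned before the data were examined. All other tests of causes in this part were chosen after the results were seen.

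The Ko1 effect differed between the stages for 113 genes by edgeR. In 5 of 30 draws of the genotype labels within each stage, the real one among them, as many genes were called or more. A draw can keep or reverse the real Ko1 grouping at 1 stage and so hold the Ko1 effect itself. The draws therefore cannot decide on chance, which is not excluded. The highest other draw called 4513 genes and 25 other draws called 0, which points to a structure of the samples. Without the library labelled WT 5DAF replicate 3 the count was 84, and 66 of these genes were among the 113, which argues against that library as the whole cause. The change of the OE effect passed for 0 genes by edgeR (1226 at an unadjusted p under 0.05, 13 by DESeq2), and 30 of 30 draws called as many, with a highest other count of 4.

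Of the named genes, LOC_Os01g43750, a cytochrome P450 gene, had a change of −2.60 and kept its call without each single library. The change was 11.03 for LOC_Os08g20420 (MGD2), 9.82 for lipase gene LOC_Os11g43760 and 9.68 for LOC_Os04g47330. These 3 values come from genes with few or 0 counts in a WT group and depend on the prior count. None of the 3 passed without the library labelled WT 5DAF replicate 3 (8.48, 5.51 and 6.55, with edgeR adjusted p = 0.391, 0.512 and 0.305), and those values rest on low WT counts too. Over all leave-one-out fits the edgeR adjusted p ran from 0.00254 to 0.391, from 0.00249 to 0.512 and from 0.0129 to 0.305. LOC_Os08g20420 passed in every other such fit. LOC_Os11g43760 also did not pass without any 1 WT 15DAF library (9.21 to 12.43). LOC_Os04g47330 passed only without WT 5DAF replicates 1 or 2 or Ko1 15DAF replicate 2. The calmodulin-like gene LOC_Os11g04560 had a change of −3.09 and passed only without Ko1 15DAF replicate 2 among 12 leave-one-out fits (−3.34 to −2.56). The EF hand gene LOC_Os03g59770 had a change of −2.72 and passed only without WT 15DAF replicate 3 or Ko1 15DAF replicate 2 (−3.08 to −2.38). LOC_Os06g38120 had a change of −1.17 and LOC_Os11g47240 one of 1.302 (edgeR adjusted p = 0.0441 for both), and these are the 2 named genes called for Ko1 at 5DAF.

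Among the lists, the mean change of the Ko1 effect was 2.13 log2 units for the Pi list, 0.96 for chlorophyll synthesis, 0.62 for starch and sucrose, 0.53 for light reactions, 0.47 for the Calvin-Benson cycle, −0.23 for ribosomal proteins and −0.20 for WRKY genes. Means that include genes with 0 counts depend on the prior count. The camera adjusted p was 5.76e-15, 3.33e-05, 6.37e-05, 0.00128, 0.00150, 1.41e-12 and 0.0113. With an estimated correlation only the Pi list passed (adjusted p = 0.0183), the others running from 0.395 to 0.642. In the fit without the library labelled WT 5DAF replicate 3 the 7 values of camera were 5.90e-10, 6.81e-11, 1.1011e-05, 3.04e-07, 1.72e-07, 2.74e-12 and 0.00611, and no list passed with an estimated correlation, the lowest adjusted p being 0.1998. The mean change of the OE effect was 0.56 for starch and sucrose, −0.48 for photorespiration, −0.47 for light reactions, −0.45 for the Calvin-Benson cycle and −0.29 for chlorophyll synthesis. The camera adjusted p was 0.00198, 1.99e-05, 3.35e-08, 7.38e-05 and 0.0240, and with an estimated correlation it ran from 0.487 to 0.642. Leaving out that library, the 5 values of camera were 2.58e-05, 0.00489, 8.54e-05, 0.0118 and 0.652, so the call of chlorophyll synthesis ended, and no list passed with an estimated correlation. The median changes in that fit were 0.39, −0.29, −0.36, −0.21 and −0.08 in the same order, whereas the sizes above are means.

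The library labelled WT 5DAF replicate 3 resembled the Ko1 libraries. Of 25 genes read in every WT 15DAF library and at 3 counts or fewer in Ko1 at 15DAF, it had 24 at 3 counts or fewer, against 0 and 0 in the other WT 5DAF libraries and 23, 25 and 24 in the Ko1 5DAF libraries. A wrong label, with the library holding leaf of the Ko1 line, may explain this, and an origin in another plant with a background like that of Ko1 was not tested apart. A swap with a Ko1 5DAF library was argued against, since at most 2 of the 25 genes exceeded 3 counts in any of them. Low phosphate supply of a wild-type plant was argued against, since 12 of 12 genes off in both Ko1 and OE were at 3 counts or fewer in this library too.

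The same 12 genes, read in WT and near 0 in both Ko1 and OE at 15DAF, form the second pattern. Library depth was argued against, since at 5DAF, a stage not used to choose the genes, WT replicates 1 and 2 predict at least 87.6 counts per gene over the 3 libraries of Ko1 or OE, against at most 1 observed. A graded response to the amount of OsPHO1;2 transcript was argued against, since 12 of 12 genes lay below WT 5DAF replicates 1 and 2 in all 6 Ko1 and OE libraries of 5DAF, where OsPHO1;2 was 2.42 CPM in Ko1 and 8.18 CPM in OE against 2.50 CPM in WT. A difference of genetic background between the WT plants and the transgenic lines may explain the pattern, as 12 of 12 genes were at 3 counts or fewer in each of the 6 Ko1 and OE libraries of 5DAF. Effects of the OsPHO1;2 changes themselves on these genes were not tested apart from such a background.

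The third pattern is the lower count of genes for Ko1 at 5DAF (3) than at 15DAF (2240). The count at 15DAF was 1.098 times the count at 5DAF without the library labelled WT 5DAF replicate 3. That library is therefore a likely cause of the low count, found and tested on the same data. No biological explanation for the difference between these 2 counts was tested.

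For the comparisons of 3 libraries with 3, there are 10 splits, the real one included, so the share of splits cannot be under 0.05. For Ko1 against WT at 5DAF the real count was 3, 3 splits called as many, and the highest other was 1647, for WT replicates 1 and 2 with Ko1 replicate 1 against the rest, which points to a structure of the samples. For the other comparisons 1 split, the real one, called as many. The real count and the highest other were 2240 and 1 for Ko1 against WT at 15DAF, 8 and 0 for OE against WT at 5DAF, 5 and 0 for OE against WT at 15DAF, 3418 and 0 for time in WT, 4102 and 3 for time in Ko1, and 5455 and 0 for time in OE.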

How the results depend on the processing

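The fit without 2 libraries (WT 5DAF replicate 3 and Ko1 5DAF replicate 3), and the use of the fit without WT 5DAF replicate 3 for contrasts that do not hold it, were chosen after seeing the data. The planned pseudocount alternative was not run, since it did not apply to counts. Where a value moved, the cause was not tested unless stated.

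DESeq2 called 760 genes for Ko1 at 5DAF, 3498 for Ko1 at 15DAF, 94 for OE at 5DAF, 25 for OE at 15DAF, 307 for the change of the Ko1 effect and 13 for that of the OE effect. With DESeq2 OsPHO1;2 passed for OE at 15DAF (2.77) and for time in Ko1 (1.34). Without a low-count filter the counts were 72 for Ko1 at 5DAF, 42 for OE at 5DAF and 26 for OE at 15DAF, where OsPHO1;2 passed (2.77). With the replicate number as a block they were 1 for Ko1 at 5DAF and 3 for OE at 15DAF. At adjusted p under 0.01 edgeR called 0 and 619 for Ko1 at 5DAF and 15DAF, 4 and 3 for OE, 1681, 2274 and 3265 for time in WT, Ko1 and OE, and 26 for the change of the Ko1 effect. Fitting only the groups of the contrast gave 0 for Ko1 and 5 for OE at 5DAF, 52 for OE at 15DAF, 2639 for time in Ko1 and 30 for the change of the Ko1 effect, and OsPHO1;2 passed for Ko1 at 15DAF (1.27). Without the 2 libraries the counts were 1086 for Ko1 and 38 for OE at 5DAF and 47 for the change of the Ko1 effect, and IPS1 over time in WT was 1.81, on 1 count at 5DAF. RLE size factors moved no count by over 1.5 times.

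Leaving out 1 library gave 0 to 2803 genes for Ko1 and 4 to 60 for OE at 5DAF, 814 to 3079 for Ko1 and 3 to 29 for OE at 15DAF, 1907 to 3114, 2725 to 4549 and 3943 to 5918 for time in WT, Ko1 and OE, and 35 to 142 and 0 to 3 for the changes of the Ko1 and OE effects. OsPHO1;2 ran from 2.15 to 3.21 for OE at 15DAF and from 0.48 to 1.51 for time in OE, and IPS1 over time in WT from −12.94 to 1.77, both fitted on 0 or 1 counts in a group. The highest Ko1 count at 5DAF and the positive IPS1 value came without the library labelled WT 5DAF replicate 3. Without it the Ko1 and OE effects had a correlation of 0.432, a covariance of 0.409 and 31 shared calls at 5DAF, and a covariance of 0.262 and 23 shared calls at 15DAF. Over only the genes called in either comparison, the correlation was −0.033 and the covariance −0.28 at 5DAF, over 11 genes, too few to show a change of sign, and 0.531 and 1.39 at 15DAF, over 2243. Camera called 56 of 135 list tests, 2 with an estimated correlation, and fry 26.

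Of 207 results of named genes, 44 calls ended at adjusted p under 0.01, 10 with the block, 3 without a filter and 1 with RLE, and 1 was gained without a filter. Of 204, 16 ended in fits of only the groups of the contrast, and 5 ended and 2 were gained with DESeq2. In the fit without WT 5DAF replicate 3, 16 ended, 11 were gained and 1, IPS1 over time in WT, changed its fitted sign.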

Other observations

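Families of genes with the same description gave further biology, in a one-sided Fisher exact test chosen after the results were seen and adjusted by Benjamini-Hochberg over 399 families of at least 8 genes. Members of a family are not independent. In Ko1 leaves at 15DAF aquaporin genes were higher in 9 of 23 cases (Fisher adjusted p = 0.00148), glycerophosphodiester phosphodiesterase genes in 5 of 10 (0.0299) and cytochrome P450 genes in 20 of 136 (0.0422). Regulatory subunit genes of the 26S protease were lower in 7 of 11 cases (9.26e-06), T-complex chaperonin genes in 6 of 20 (0.00950) and PPR repeat genes in 16 of 129 (0.00950). Over time in WT, MATE efflux genes rose in 13 of 36 cases (4.53e-04) and DnaK chaperone genes in 8 of 18 (0.00466), and peroxidase genes fell in 12 of 41 (0.0281). In the fit without the library labelled WT 5DAF replicate 3, MATE genes rose in 11 of 37 cases (0.00217, adjusted over 411 families), DnaK genes in 8 of 18 (0.00217) and peroxidase genes fell in 14 of 45 (0.00320).

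In Ko1 leaves at 5DAF, without the library labelled WT 5DAF replicate 3, several families held more lower genes than expected, of which 3 are given. PPR repeat genes were lower in 38 of 130 cases (Fisher adjusted p = 3.56e-11, over 411 families), mTERF genes in 10 of 29 (0.00269) and DEAD-box helicase genes in 13 of 51 (0.00524). SHR5-like receptor kinase genes were higher in 9 of 17 cases (6.35e-05) and auxin response factor genes in 8 of 24 (0.00420). With all libraries edgeR called 3 genes in that comparison, so families were not tested there.

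Of the 25 genes read in WT and off in Ko1 at 15DAF, 14 were described as transposon genes (56%), against 2.57% of 15584 genes read in every WT 15DAF library (Fisher exact two-sided p = 1.48e-16). Of the 12 off in both lines 6 were (Fisher exact two-sided p = 2.23e-07). The OE libraries had 3 counts or fewer for 16, 17 and 17 of the 25 at 5DAF and 12, 16 and 18 at 15DAF. The lowest count belonged to OE 15DAF replicate 1, so the OE 15DAF libraries did not read these genes alike. In it LOC_Os05g36240 read 6.67 CPM against 0 and 0 in replicates 2 and 3, and LOC_Os07g05850 read 7.45 against 0.257 and 0. LOC_Os06g49350 went the other way, at 17.0 against 39.5 and 39.5. The cause was not tested. Of 18 genes read in Ko1 and off in WT at 15DAF, the library labelled WT 5DAF replicate 3 read 14 above 3 counts, the other WT 5DAF libraries 1 and 2, and the Ko1 5DAF libraries 13, 14 and 12. A score over 1374 genes that differed by at least 2-fold between Ko1 and WT at 15DAF was 0.56 in that library, −0.53 and −0.57 in the other WT 5DAF libraries, and 0.39, 0.55 and 1.03 in the Ko1 5DAF libraries.

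Replicates of the same number were checked for shared deviations between groups. Of 45 pairs 5 had a correlation over 0.1, with a range from −0.205 to 0.251 and a median of 0.0221, and the own number gave the highest value in 18. The replicate numbers were not treated as pairs, and a fit with them as a block called 84 genes for the change of the Ko1 effect.

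The processing notes name a mouse genome build, whereas the counts are of rice loci. OsPHO1;2 transcript in Ko1 at 15DAF was 6.10, 6.14 and 6.07 CPM, above each WT 15DAF library. Which part of the gene these reads cover was not tested, as reads were not used here.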
